A study of Homo sapiens with 24 samples.

How the data were processed

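Human bone-marrow mononuclear cells, sorted for live cells that carry CD45, were profiled with the 10x multiome assay, which reads RNA and transposase-accessible chromatin (ATAC) from the same cell, after digitonin permeabilisation. Per the labels, each of 12 multiome libraries pooled cells of baseline and end of treatment, marked by antibody hashtags. The 24 samples are these 12 libraries and 12 hashtag libraries. The participants numbered 13, and 1 library held cells of 2 of them. Count matrices of 6 libraries, 3 from each of 2 sequencing projects, and peak lists of all 12 libraries were used. The sequencing project of a library was read from the prefix of its name. Hashtag counts were not used here, so no cell was assigned to a time point. Details of participants are not reported here.

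The matrices hold raw counts, made before deposit by the authors, whose processing notes name Cell Ranger ARC, Cell Ranger and Seurat, without versions, and the genome build GRCh38. RNA values are UMIs per gene and cell. ATAC values are transposase cut sites per peak and cell, since 64.3% to 75.8% of the nonzero values were 2 and 9.10% to 16.2% were 1, as when both ends of a fragment are counted. The peaks were called for each library separately. Barcode lists and peak lists as deposited hold no measurement.

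Cells were kept with at least 300 genes, at most 25% mitochondrial UMIs and at least 500 ATAC counts. Doublet scores were computed with Scrublet in scanpy. Its automatic threshold marked 0 and 2 cells in a pair of libraries, so the highest-scoring 0.8% of cells per 1000 barcodes were left out instead, 1560 cells in all. RNA was normalised per cell and log transformed, 3000 variable genes were scaled within each library, with values limited to 10, and 30 principal components and 15 neighbours fed Leiden clustering at resolution 1. Clusters whose name was unclear (a score margin under 0.6 and at least 60 cells) were clustered again at resolution 0.5. Clustering left out 1119 genes, namely the 373 genes of 15 program lists, variable segments of immunoglobulin and T cell receptor genes, and mitochondrial, ribosomal protein and sex-linked genes. Cluster names came from 20 marker lists, with a score of at least 1.5, a margin of at least 0.3 and at least 3 markers, and other clusters stayed unnamed. The first clustering gave 26 clusters and the final one 53, of which 35 were named. Variable genes that took part in clustering were left out of the RNA counts, because a class defined by a gene differs in it. The remaining genes can vary together with those used, so their differences are not independent of how the classes were made.

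Promoter accessibility is the sum of cut sites in peaks that overlap a window of 1 kb to either side of the start or the end of a gene. The gene table used here gives no strand, so both ends count. Of 36601 genes in the matrices 22988 were matched by symbol and 720 by synonym, and 12893 had no match and were left out. Counts were summed per library and class, and a library entered a comparison with at least 20 cells of both classes. Comparisons were tested with the quasi-likelihood test of edgeR with library as a block, TMM normalisation and filterByExpr, with a prior count of 0.5 for single-library values. A call needs a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The comparisons were HSPC-like and CD16 monocyte-like cells against CD14 monocyte-like cells (5 libraries each), cytotoxic against naive T-like cells and precursor against mature B-like cells (6 libraries each). They covered 698 against 5689, 1661 against 6058, 796 against 828 and 680 against 8140 cells. Receptor genes were tested in each of 12 classes against the mean of the others. Gene lists were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one. With 5 or 6 libraries the latter has little power, so a list that did not pass it is not shown to be unchanged. DESeq2's Wald test was the second tool. All tests are two-sided.

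Where a class had 0 counts of a gene, the fold is a bound computed from 3 counts over the group. Where it had 1 to 3, a ratio with a 95% counting interval (exact binomial) is given. Floors and intervals cover counting error only and take counts as independent. Cut sites mostly come in pairs from the same fragment, so in accessibility the bounds are too high and the intervals too narrow. Correlations across genes are descriptive. Counts were also simulated from pooled profiles of the summed counts and the fitted dispersions, with 200 genes changed. On them the edgeR steps called 82% to 99% of genes changed 3-fold and 98% to 100% of genes changed 6-fold. They called 2 to 12 unchanged genes per comparison. Clustering was not rerun, so this is not the rate of false calls for the real classes.

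The comparisons, gene and marker lists, call limits, first set of alternatives and the rule for naming genes were fixed before the data were examined. The rule leaves out genes on chromosome Y, XIST, TSIX, immunoglobulin and T cell receptor segments, mitochondrial genes and clone names. For accessibility it names the 6 largest calls in each direction with the same direction in every library, taking 1 gene where intervals overlap. For RNA it names the largest such call in each direction from each program list. FFAR2, HCAR2, AHR, INSR, LEPR, ADIPOR1, IL1B and TNF are named by rule wherever tested, and across the 12 classes where called. The rule also asks for the class markers in accessibility; they are given as counts, and those named were chosen after their values were seen; HCAR2 had too few UMIs for a test by RNA in any comparison. Genes given beside these as other-class markers (NKG7 and HBB by RNA), and MALAT1, FOS, JUN and RGCC, and the receptor genes given for more classes than the rule asks, were chosen after their values were seen. The program lists are metabolite sensing, hormone receptors (with glucose transporters and insulin receptor substrates), deacetylases and chromatin, NF-kB and inflammation, interferon response, immediate early genes, MHC class II, checkpoint, homing, cell cycle, oxidative phosphorylation, glycolysis, fatty acid oxidation, cholesterol and plasma cell niche.

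Alternatives were DESeq2's size factors (RLE) in edgeR, DESeq2's test, no low-count filter, no library block, 1 sequencing project alone, each library left out in turn, clustering at resolution 0.5 or 2, predicted doublets kept, a strict cell filter (at least 500 genes, at most 10% mitochondrial UMIs) and promoter windows of 5 kb. For peak lists they were an overlap of at least 0.5 of the peak and only chromosomes 1 to 22. Added after the data were seen were scaling over all libraries, equal depths of both classes, whole genes with 1 kb flanks and fragments instead of cut sites, and a test of the difference between projects. Class shares and peak lists carry no test. Peaks were merged over lists where they overlapped by at least 1 base.

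Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.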

Results

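Bone-marrow mononuclear cells of 13 participants with precursor disorders of multiple myeloma, a cancer of plasma cells, were sorted for live cells that carry CD45, a surface protein of blood cells. RNA and open chromatin were read from the same cells (10x multiome). The study, by its title, concerns a high-fiber plant-based diet, and each of the 12 multiome libraries pooled a participant's cells from baseline and from the end of treatment. In 1 library the cells of 2 participants were pooled. The labels also list 12 hashtag libraries, whose counts would assign each cell to its time point. They were not used here, so baseline against end of treatment was not tested, and every comparison below is between cell classes within libraries.

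Count matrices of 6 libraries, from 7 participants, were analysed, 3 from each of 2 sequencing projects, as read from the prefix of the library names. These libraries held 3512 to 9030 cell barcodes, 10311542 to 22008746 RNA molecules (UMIs) and 25423280 to 70920911 transposase cut sites in peaks. After filtering, 27193 cells remained, 2314 to 6552 per library, with library medians of 1830 to 2316.5 UMIs and 5383 to 10060.5 cut sites per cell. Peak lists of all 12 libraries were compared with each other. The library is the replicate throughout, n is the number of libraries, and errors after ± are standard deviations (SD) between libraries unless a standard error (SE) is named. A gene was called at an adjusted p under 0.05 in edgeR with a log2 fold change of at least 1 in size. Levels are given in CPM, counts scaled by edgeR to a common total per library and class. Each called gene named below had the same direction in all libraries of its comparison except where a smaller number is given.

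Clustering on RNA gave 13 named cell classes, each called "-like" because the name rests on marker RNA alone. Mature B-like cells were the most numerous class, at 29.2% ± 13.6 of kept cells (n = 6), followed by CD14 monocyte-like cells at 22.5% ± 13.3. Natural killer (NK)-like cells made up 7.02% ± 2.53, CD16 monocyte-like cells 5.70% ± 6.58 and plasma-like cells 5.44% ± 6.23. Plasmacytoid dendritic (pDC)-like cells made up 4.72% ± 5.13, and hematopoietic stem and progenitor (HSPC)-like cells 3.49% ± 5.13. Precursor B-like cells made up 3.08% ± 3.32, naive T-like cells 2.99% ± 1.43 and cytotoxic T-like cells 2.88% ± 0.728. Conventional dendritic (cDC)-like cells made up 2.24% ± 1.47, erythroid-like cells 1.28% ± 1.15 and myeloid progenitor-like cells 0.302% ± 0.206. A further 9.18% ± 4.76 of the cells stayed unnamed, among them T cell clusters with markers of more than 1 T cell class. Also unnamed was a cluster of 173 cells with MEIS1, CRHBP and ERG among its top genes. Another, of 88 cells, had CXCL3, CXCL2 and CXCL8 among its top genes. Both were split from a first cluster that also gave HSPC-like clusters, and neither counts in the HSPC-like class.

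**Figure D1:**
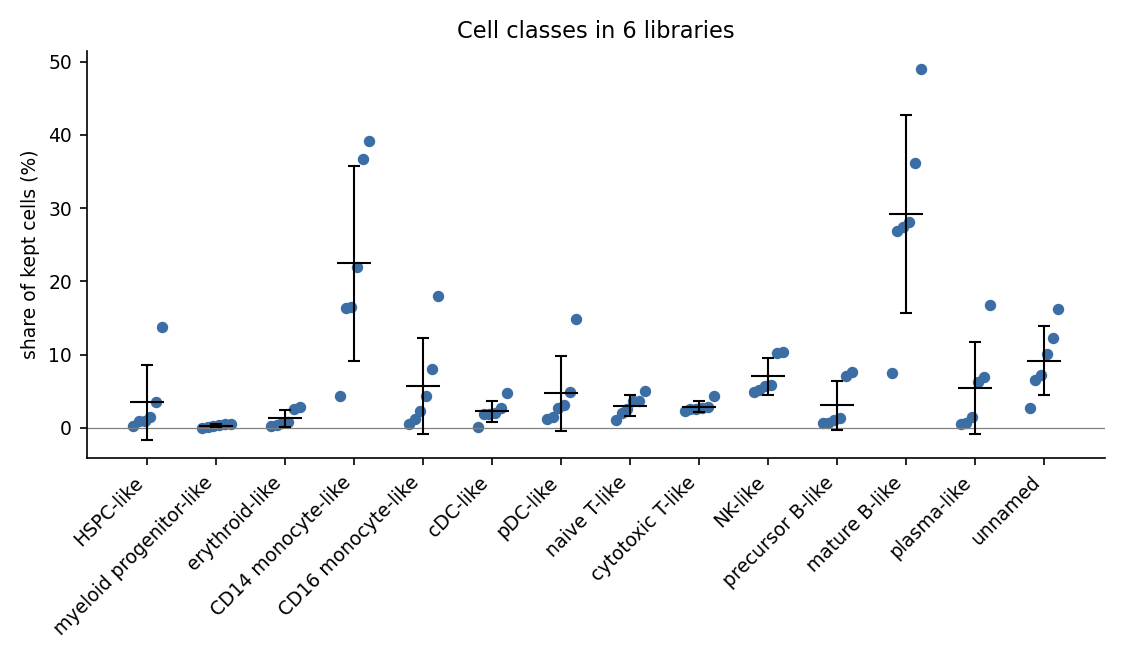
Share of kept cells (%) in each cell class; each point is 1 of 6 libraries, the horizontal bar is the mean and the error bar 1 SD. Mature B-like cells average 29.2% and CD14 monocyte-like cells 22.5%, and the spread between libraries is as large as the mean for the HSPC-like, pDC-like, plasma-like, CD16 monocyte-like and precursor B-like classes.

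Class shares varied widely between libraries, and no test was made on them. They also depended on the cell filter. The strict filter gave far lower shares of CD14 monocyte-like and cDC-like cells and higher shares of pDC-like and plasma-like cells, as given below. Without library 1 the mean HSPC-like share was 1.45% and the mean pDC-like share 2.70%. The mean plasma-like share was 3.17% without library 2, and the mean CD16 monocyte-like share 3.25% without library 7. Plasma-like cells made up 9.99% ± 5.87 of the cells in the first sequencing project and 0.890% ± 0.540 in the second (n = 3 each). CD14 monocyte-like cells made up 14.2% ± 9.01 and 30.8% ± 12.5.

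HSPC-like cells differed from CD14 monocyte-like cells in chromatin along the genes that mark either class. Promoter accessibility of KIT, the receptor for stem cell factor, was higher in HSPC-like cells (log2 fold change 2.43, SE 0.222, adjusted p = 8.49e-09; 84.5 ± 9.87 against 17.5 ± 9.21 CPM, n = 5). MECOM, a transcription factor of blood stem cells, rose by 2.37 (SE 0.197) and CD34, a surface marker of stem cells, by 2.17 (SE 0.504, in 4 of 5 libraries). S100A12 and MNDA, expressed in myeloid cells, were lower, at log2 -2.91 (SE 0.458) and -4.47 (SE 0.680), and without library 1 MNDA was at -9.38. Of 15 HSPC markers 12 were called higher, and of 10 CD14 monocyte markers 9 were called lower, in a modality that took no part in defining the classes. Without library 6 SPINK2 (main value 1.28) was at 1.15 with adjusted p = 0.0868, and CDK6 (1.24), FLT3 (1.06) and CD14 (-1.17) were at 0.91, 0.87 and -0.996, under the fold limit. FLT3 was also under it without library 8 (0.99).

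Promoter accessibility covers peaks within 1 kb of either end of a gene, since the gene table used gives no strand. Over 15784 genes tested in 5 libraries, 1716 were more and 930 less accessible in HSPC-like cells. The largest increases were at PALM2-AKAP2 (log2 5.18, SE 0.523), DNAH9 (5.05, SE 0.488), SLC1A6 (4.66, SE 0.737), ARHGAP28 (4.59, SE 0.431), MPDZ (4.49, SE 0.550) and CABCOCO1 (4.43, SE 0.394). DNAH9 (ENSG00000007174) lies on chromosome 17 at 11598470 to 11969748 of GRCh38. The largest decreases were at SRI, CPM, C2orf91, MNDA, HAL and TSPAN16. Without library 1 HAL went from -4.41 to -9.51 and C2orf91 from -4.64 to -9.22, values that depend on the prior count. HSPC-like cells held 0 cut sites at SRI. At a floor of 3 counts over the group this was at least 11.0-fold less than in CD14 monocyte-like cells, if cut sites were independent. CPM, with 3 cut sites, was 31.4-fold lower (95% counting interval 10.7 to 153). C2orf91, also with 3, was 22.3-fold lower (7.59 to 108). Cut sites mostly come in pairs from the same fragment, so this floor and these intervals understate the counting error. When cut sites were counted over whole genes, PALM2-AKAP2 and SRI changed sign, to -0.27 and 0.29.

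Most cell cycle genes had higher RNA in HSPC-like cells, and many inflammatory, homing and metabolite sensing genes lower RNA, though no list passed a set test with an estimated correlation. These are genes that took no part in clustering, though they can vary together with genes that did, which favours differences in advance. Of 30 cell cycle genes 24 were higher and 1 lower, led by the thymidylate synthase gene TYMS (log2 4.28, SE 0.533, 43.8 ± 11.1 against 2.93 ± 3.45 CPM, higher in 5 of 5 libraries). That list had adjusted p = 0.263 with an estimated correlation. Of 25 NF-kB and inflammatory genes 15 were lower and 1 higher (adjusted p = 0.199 with an estimated correlation), with TNFAIP2 at log2 -4.11 (SE 0.369). The HSPC-like class does not hold the unnamed cluster led by CXCL3, CXCL2 and CXCL8, which came from the same first cluster. The cytokine genes IL1B and TNF were lower by RNA, at -2.29 (SE 0.329) and -3.34 (SE 0.799), and in accessibility, at -1.28 (SE 0.252) and -3.19 (SE 0.440).

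Of 20 genes that sense metabolites 13 had lower RNA in HSPC-like cells and 1 higher, with adjusted p = 0.175 for the list with an estimated correlation. FFAR2, a receptor for short-chain fatty acids such as those gut bacteria make from fiber, was at log2 -3.53 (SE 0.556, adjusted p = 3.34e-05; 1.74 ± 2.62 against 23.1 ± 7.87 CPM). AHR, a receptor for aromatic compounds, was at -1.57 (SE 0.262). CYP1B1, an AHR target, had 1 UMI in HSPC-like cells and was 50.8-fold lower (95% counting interval 9.05 to 2012). NR1H3, the liver X receptor alpha gene, was the higher member (1.495, SE 0.573), and its call ended without library 2 (1.46, adjusted p = 0.0802) and without library 8 (1.55, adjusted p = 0.0626). In accessibility 11 of 27 metabolite sensing genes were lower and 0 higher, among them FFAR2 (-2.12, SE 0.245) and the niacin and butyrate receptor gene HCAR2 (-3.11, SE 0.525). AHR, INSR, LEPR and ADIPOR1 were at -0.45, -0.67, 0.29 and -0.05 in accessibility and not called.

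Other lists moved in part between HSPC-like and CD14 monocyte-like cells. Of 15 homing genes 11 were lower (adjusted p = 0.175 with an estimated correlation), with the chemokine receptor gene CCR1 at log2 -5.20 (SE 0.438). Of 24 immediate early genes 12 were lower (0.263 as adjusted p with an estimated correlation), with IER3 at -3.89 (SE 0.365). Of 12 MHC class II genes 8 were lower, of 29 interferon response genes 13 lower and 1 higher, each list at adjusted p = 0.442 with an estimated correlation. Of 16 plasma cell niche genes 10 were lower and 3 higher (adjusted p = 0.263 with an estimated correlation). VEGFA, an angiogenic growth factor, was at -3.87 (SE 0.344), and IL7, a lymphoid growth factor, at 1.44 (SE 0.323). Of 10 checkpoint genes 5 were lower and 1, TOX (5.81, SE 0.399), higher (adjusted p = 0.199 with an estimated correlation). The hormone receptor list, which also holds glucose transporters and insulin receptor substrates, went both ways, with 5 of 19 genes higher, among them the thyroid hormone receptor THRB (5.50, SE 0.435), and 9 lower, among them IGF2R (-3.33, SE 0.387) and ADIPOR1 (-1.34, SE 0.312), while INSR and LEPR were at -0.64 and 0.24. Lower calls prevailed among glycolysis genes (8 of 18, 2 higher), deacetylase and chromatin genes (8 of 19, 1 higher) and cholesterol genes (4 of 20, 0 higher). Oxidative phosphorylation (1 higher and 2 lower of 33) and fatty acid oxidation (3 higher and 2 lower of 19) moved little. The fatty acid oxidation list had a median log2 of -0.11 and a mean of -0.05, while its set test pointed up.

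In all, 10455 genes outside the clustering were tested in this comparison, with 1631 higher and 2369 lower in HSPC-like cells (n = 5). Of 15 lists 9 were called with a preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.175. Counts adjusted over the list alone were the same for all 15 lists. RNA of NK markers was also lower, with 3 of 4 called, and of 10 plasma cell markers 5 were higher and 1 lower. The NK marker list shares FCGR3A with the CD16 monocyte list, so such calls need not come from NK cells. MALAT1, an abundant nuclear RNA, was lower (log2 -1.28, SE 0.158; 15403 against 37234 CPM). The accessibility count was 1439 in the first sequencing project alone and 1694 with no library block, against 2646. The RNA count was 2485 in the first project alone and 2347 at equal depths, against 4000.

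CD16 monocyte-like cells differed from CD14 monocyte-like cells in RNA of single interferon-induced, inflammatory, homing and lipid uptake genes, some higher and some lower. IFITM3, an interferon-induced antiviral gene, was higher by log2 2.35 (SE 0.166, adjusted p = 1.00e-10; 476 ± 226 against 98.7 ± 73.1 CPM, n = 5). CX3CR1, the fractalkine receptor of patrolling monocytes, was higher by 2.20 (SE 0.289). CCR2, the receptor that draws monocytes out of the marrow, had 2 UMIs in CD16 monocyte-like cells and was 40.8-fold lower (95% counting interval 11.2 to 339). CD36, a scavenger receptor for fatty acids, was at -2.15 (SE 0.203).

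Of 32 interferon response genes 6 were higher and 0 lower in CD16 monocyte-like cells, and 7 were higher when adjusted over the list alone. The list had adjusted p = 0.421 with an estimated correlation. Inflammatory RNA moved both ways. TNF was higher (log2 1.96, SE 0.349), while IL1B (-1.23, SE 0.229) and CXCL2 (-1.66, SE 0.316) were among 9 of 25 NF-kB and inflammatory genes that were lower (adjusted p = 0.677 with an estimated correlation). Of 16 homing genes 5 were higher and 5 lower.

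Metabolite sensing genes also moved apart between the monocyte-like classes, with 3 of 21 higher and 6 lower. GPBAR1, a bile acid receptor, was higher (log2 1.25, SE 0.208), and AHR was lower (-1.47, SE 0.201; 207 ± 157 against 507 ± 215 CPM). FFAR2 was at 0.71 (SE 0.225, adjusted p = 0.0207), under the fold limit, and higher in 4 of 5 libraries. Of 15 genes on the hormone receptor list 2 were higher and 4 lower, with the glucose transporter genes SLC2A6 at 1.91 (SE 0.196; 246 bases from CACFD1 in the annotation) and SLC2A3 at -2.66 (SE 0.213). INSR, LEPR and ADIPOR1 were at 0.54, 0.22 and -0.60 and were not called. In accessibility FFAR2, HCAR2, AHR, INSR, LEPR, ADIPOR1, IL1B and TNF were at -0.14, -0.68, -0.23, -0.55, 0.13, 0.00, -0.37 and 0.07, none of them called.

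Of 15 plasma cell niche genes 3 were higher, with the growth factor gene FLT3LG at log2 1.64 (SE 0.368), and 5 lower, with the cytokine gene OSM at -2.92 (SE 0.436); 6 were lower when adjusted over the list alone. Of 20 cholesterol genes 5 were lower, and SCD, with 2 UMIs in CD16 monocyte-like cells, was 13.6-fold lower (95% counting interval 3.64 to 114); its call ended without library 3 (adjusted p = 0.0515) and without library 8 (0.121). Few members moved in the glycolysis list (1 higher and 2 lower of 17) and the immediate early list (3 lower of 24). The glycolysis gene HK3 (1.06, SE 0.184) was at 0.89 without library 3. Of 8 checkpoint genes 2 were lower. The checkpoint and glycolysis lists had medians of 0.25 and 0.15, means of -0.06 and -0.12 and set tests that pointed down. In MHC class II 1 of 12, HLA-DMB (-1.02, SE 0.220), was lower, and its call ended without library 3 (-0.75) and without library 7 (-0.84). PPARGC1B (1.06, SE 0.197), 1 of 19 fatty acid oxidation genes, was higher, and without library 8 it was at 0.86. CENPE, 1 of 11 cell cycle genes, was called higher at 1.06 (SE 0.367) but not when adjusted over the list alone, nor without library 2 (0.86), 3 (0.82) or 7 (1.24, adjusted p = 0.103). Of 33 oxidative phosphorylation and 18 deacetylase and chromatin genes edgeR called 0, with 0 past the fold limit at an unadjusted p under 0.05 and 0 called by DESeq2.

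Promoter accessibility of the monocyte-like classes differed almost one-sidedly, with 25 of 15988 genes higher and 334 lower in CD16 monocyte-like cells. The largest increases were at TLE2 (log2 1.46, SE 0.436), REC8 (1.38, SE 0.148), TMPRSS13 (1.35, SE 0.348), MYBPHL (1.15, SE 0.238), DGKG (1.14, SE 0.184) and CCDC116 (1.13, SE 0.219). The largest decreases were at TLL1, BMPR1B-DT, MCHR1 (-3.25, SE 0.359), ULBP3 (-2.60, SE 0.335), JPH1 (-2.46, SE 0.716) and KIAA1211L (-2.36, SE 0.534). TLL1 had 0 cut sites, at least 5.48-fold less, and BMPR1B-DT had 1 (27.0-fold lower, 95% counting interval 4.76 to 1077). The bound and the interval take cut sites as independent, though most come in pairs, and so understate the counting error. The TLE2 call ended without library 3 (adjusted p = 0.064), 6 (0.0922), 7 (0.0642) or 8 (0.0824), and the TMPRSS13 call without library 7 (0.184). MYBPHL without library 2 (0.99) and DGKG without library 7 (1.00) fell just under the fold limit. The BMPR1B-DT call ended without library 2 (0.0507 as adjusted p), 3 (0.13) or 8 (0.112), and the JPH1 call without library 3 (0.111) or 8 (0.0632). MCHR1 (ENSG00000128285) encodes a receptor for melanin-concentrating hormone. Of 10 CD16 monocyte markers edgeR called 0, with 0 past the fold limit at an unadjusted p under 0.05 and 0 called by DESeq2, and CDKN1C at 0.69 (SE 0.104, adjusted p = 4.83e-08), RHOC at 0.75 and LRRC25 at 0.80 were under the fold limit. Of 10 CD14 monocyte markers only VCAN was called, and lower (-1.11, SE 0.275, in 4 of 5 libraries), with the call ending without library 3 (-0.84), 7 (-0.94) or 8 (adjusted p = 0.0506).

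For RNA, 9647 genes outside the clustering were tested, with 410 higher and 606 lower (n = 5). With a preset correlation 3 of 15 lists were called and with an estimated one 0. Of 6 NK markers 3 were called higher by RNA in CD16 monocyte-like cells. Among them were the NK and T cell gene NKG7 at log2 1.48 (SE 0.219) and FCGR3A. FCGR3A is also on the CD16 monocyte list that named the class, so its call was favoured in advance. Of 6 cDC markers 4 were lower and 1 higher. With no library block 431 RNA calls and 100 accessibility calls were left. The accessibility count was 26 in the first project (2 libraries), 5 under the stricter cell filter (2 libraries) and 221 without library 7.

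Promoters of the granule genes NKG7 and GZMB and the chemokine genes CCL4 and CCL5 were more open in cytotoxic than in naive T-like cells. Cytotoxic T-like cells also had higher RNA of some interferon response and chemokine genes. In accessibility, NKG7, a granule gene of cytotoxic cells, was higher by log2 4.24 (SE 0.425, adjusted p = 4.33e-11; 78.7 ± 27.7 against 3.15 ± 5.21 CPM, n = 6). The granzyme gene GZMB was higher by 4.38 (SE 0.653), and the chemokine genes CCL4 and CCL5 by 4.13 (SE 0.524) and 4.02 (SE 0.407). CD8A, the coreceptor of cytotoxic T cells, was higher by 1.13 (SE 0.238), and by 0.91 without library 6, under the fold limit. Of 7 cytotoxic T markers tested 4 were called higher and of 9 naive T markers 1, LEF1-AS1, lower (-2.55, SE 0.671), in 3 of 6 libraries; its call ended without library 2 (adjusted p = 0.324) and without library 8 (0.235). LEF1 itself, a transcription factor of naive T cells, was at -2.42 (SE 0.781, adjusted p = 0.0577), and was called without library 1 (0.0329) or 3 (0.0303).

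Over 12658 genes, accessibility was higher at 186 and lower at 163 in cytotoxic T-like cells. Besides NKG7, GZMB and CCL4, the largest increases were at KIR2DL4, KRT74 (log2 5.21, SE 0.499) and PRDM11 (4.89, SE 0.701). KIR2DL4, a killer cell receptor gene, had 78 cut sites in cytotoxic T-like and 0 in naive T-like cells. This is at least 25.3-fold more if cut sites were independent, but most come in pairs, so the bound is too high. The largest decreases were at BEND5 (-4.15, SE 0.640), ZNF471 (-3.66, SE 0.510), ZNF667-AS1 (-3.60, SE 0.622), MB21D2 (-3.54, SE 0.757), DYDC1 (-3.21, SE 0.993) and FAM151B (-3.09, SE 0.509). The DYDC1 call ended without library 6 (adjusted p = 0.166), 7 (0.0677) or 8 (0.201). Of 26 interferon response genes edgeR called 0 in accessibility, with 1 past the fold limit at an unadjusted p under 0.05 and 0 called by DESeq2. AHR, INSR, LEPR, ADIPOR1 and TNF were at -0.56, -2.14, -0.30, -0.22 and 1.14, not called.

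By RNA, the chemokine gene CCL3L1 was higher by log2 5.99 (SE 0.536), and by 3.58 without library 7, and the interferon-induced gene IFIT3 by 3.48 (SE 0.345, 176 ± 201 against 14.8 ± 13.0 CPM, higher in 6 of 6 libraries). Of 19 interferon response genes 8 were higher and 0 lower, and of 14 NF-kB and inflammatory genes 4 were higher and 0 lower. Of 9 MHC class II genes 4 were higher, and of 7 checkpoint genes 3, led by TOX (3.66, SE 0.325). Each of these lists had adjusted p = 0.172 with an estimated correlation. HLA-DQB1, at 1.31 (SE 0.312), fell to -0.92 when predicted doublets were kept. Of 19 immediate early genes 10 were higher, among them the phosphatase gene DUSP2 (2.04, SE 0.272), and 1 was lower when adjusted over the list alone; the list had adjusted p = 0.486 with an estimated correlation. For some of them the difference depended on the sequencing project, with FOS at 0.01 in the first and 2.16 in the second, JUN at -0.29 and 1.41, and DUSP2 at 1.07 and 2.88. TNF was higher by 2.08 (SE 0.561) in 5 of 6 libraries, and its call ended without library 6 (1.72, adjusted p = 0.0592) and without library 7 (1.75, adjusted p = 0.0559), while without library 2 it was at 3.47.

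Other lists moved in part between the T cell classes, in both directions. The integrin gene ITGAL was higher (log2 1.99, SE 0.230), among 2 higher and 2 lower of 11 homing genes (adjusted p = 0.486 with an estimated correlation). Of 8 plasma cell niche genes 3 were higher and 2 lower (adjusted p = 0.604 with an estimated correlation), with IL6ST, the shared receptor chain of the interleukin 6 family, at -1.91 (SE 0.192). TNFSF14 had 1 UMI in naive T-like cells and was 55.0-fold higher (95% counting interval 9.43 to 2215). Of 9 genes on the hormone receptor list 2 were higher and 2 lower, with the insulin receptor substrate IRS2 at -3.01 (SE 0.272). Of 12 metabolite sensing genes 2 were higher, with RXRA at 1.75 (SE 0.408) but at 0.24 when predicted doublets were kept, while AHR was at 0.35 (SE 0.229, adjusted p = 0.295). Cholesterol genes gave 1 higher and 1 lower of 13, namely MVD (2.83, SE 0.447) and SC5D (-2.53, SE 0.332). HDAC9 (2.51, SE 0.276) was 1 of 2 higher among 13 deacetylase and chromatin genes, and was at 0.04 when predicted doublets were kept. LDHB (-1.39, SE 0.260) was lower among 11 glycolysis genes. HADHB (1.09, SE 0.331) was higher among 11 fatty acid oxidation genes, and its call ended without library 7 or 8 (adjusted p = 0.0895 and 0.0885). Of 26 oxidative phosphorylation genes and of 3 cell cycle genes edgeR called 0, with 0 past the fold limit at an unadjusted p under 0.05 and 0 called by DESeq2. The hormone receptor, oxidative phosphorylation and cholesterol lists had medians of 0.55, 0.08 and 0.13, while their set tests pointed down.

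In this comparison 4670 genes outside the clustering were tested by RNA, with 298 higher and 225 lower (n = 6). The RNA count also fell with no library block and under the stricter cell filter, as given below. Of 15 lists 5 were called with a preset correlation and 0 with an estimated one. RNA of NK markers was higher for 7 of 8 genes, with a median log2 of 5.19 beside 5.28 for the class's own markers, and that of innate-like T markers for 3 of 5. The NK marker list shares NKG7 with the class's own markers, and whether the class holds NK cells was not tested. The accessibility count was 188 with no library block, 46 under the stricter cell filter, 538 over whole genes, 218 without library 6 and 179 without library 8. In the first project alone (3 libraries) edgeR called 0 genes in accessibility, with 314 at an unadjusted p under 0.05, and 137 by RNA.

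Precursor B-like cells had higher RNA of most cell cycle and respiratory chain genes and lower RNA of MHC class II genes than mature B-like cells. However, no list passed a set test with an estimated correlation, and with 6 libraries this test has little power. Some clusters of the precursor class had cell cycle genes among their top genes and others did not, so these summed differences need not hold in each. MKI67, a proliferation marker, was higher by log2 7.63 (SE 0.369, adjusted p = 1.48e-16; 244 ± 122 against 1.58 ± 1.54 CPM, n = 6). ATP5MC3, a subunit of the mitochondrial ATP synthase, was higher by 2.57 (SE 0.293), and the glycolysis gene GAPDH by 3.37 (SE 0.272). HLA-DOB, which modulates peptide loading on MHC class II, was lower (-3.09, SE 0.319). The chemokine receptor CXCR5, which guides B cells to follicles, was lower by RNA (-4.55, SE 0.457) and in accessibility (-2.84, SE 0.337).

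All but 1 of the 34 cell cycle genes were higher in precursor B-like cells, 23 of 33 oxidative phosphorylation genes were higher and 0 lower, and 8 of 15 glycolysis genes were higher. All 13 MHC class II genes were lower. Of 20 NF-kB and inflammatory genes 13 were lower, and 14 when adjusted over the list alone, with the cytokine IL6 at log2 -3.88 (SE 0.583), and at -8.01 without library 2. Of 15 homing genes 8 were lower, of 12 checkpoint genes 5, and of 22 immediate early genes 15, with the nuclear receptor NR4A2 at -3.74 (SE 0.357). Each of these 8 lists had adjusted p = 0.181 with an estimated correlation. CD80, a costimulatory ligand, had 3 UMIs in precursor B-like cells and was 22.7-fold lower (95% counting interval 7.70 to 110). Its fitted log2 of -4.97 went to -8.23 without library 2. TNF was at -1.97 (SE 0.620) in 4 of 6 libraries.

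INSR, the insulin receptor gene, was higher in precursor B-like cells by RNA (log2 2.03, SE 0.250; 101 ± 28.6 against 26.2 ± 13.0 CPM) and in accessibility (1.66, SE 0.244), though over the whole gene accessibility was at -0.18. It was the higher member of 15 genes on the hormone receptor list, of which 5 were lower, with THRB at -3.45 (SE 0.529), and at -5.68 without library 1 (adjusted p = 0.328 for the list with an estimated correlation). LEPR and ADIPOR1 RNA, at 0.91 and 0.38, was not called. Of 15 metabolite sensing genes 5 were lower, with the retinoic acid receptor RARA at -1.85 (SE 0.314), and the vitamin D receptor gene VDR was higher (2.67, SE 0.579). AHR was at -1.09 (SE 0.245) in 5 of 6 libraries, and under the fold limit without library 7 (-0.89) or 8 (-0.97). Of 12 plasma cell niche genes 6 were lower, with TNFRSF13B, a receptor for plasma cell survival factors, at -3.42 (SE 0.517), and MIF was higher (2.41, SE 0.261). Of 18 cholesterol genes 6 were lower and 2 higher. The metabolite sensing, niche and cholesterol lists had adjusted p = 0.181 with an estimated correlation. Interferon response genes gave 6 lower and 2 higher of 27 (adjusted p = 0.183 with an estimated correlation), with EPSTI1 at -2.41 (SE 0.283) and HERC5 at 1.18 (SE 0.267). Of 19 fatty acid oxidation genes 6 were higher (adjusted p = 0.410 with an estimated correlation), with ACAA2 at 1.88 (SE 0.352). HDAC2 (1.57, SE 0.238) was higher and HDAC9 (-1.46, SE 0.187) lower among 19 deacetylase and chromatin genes.

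**Figure D2:**
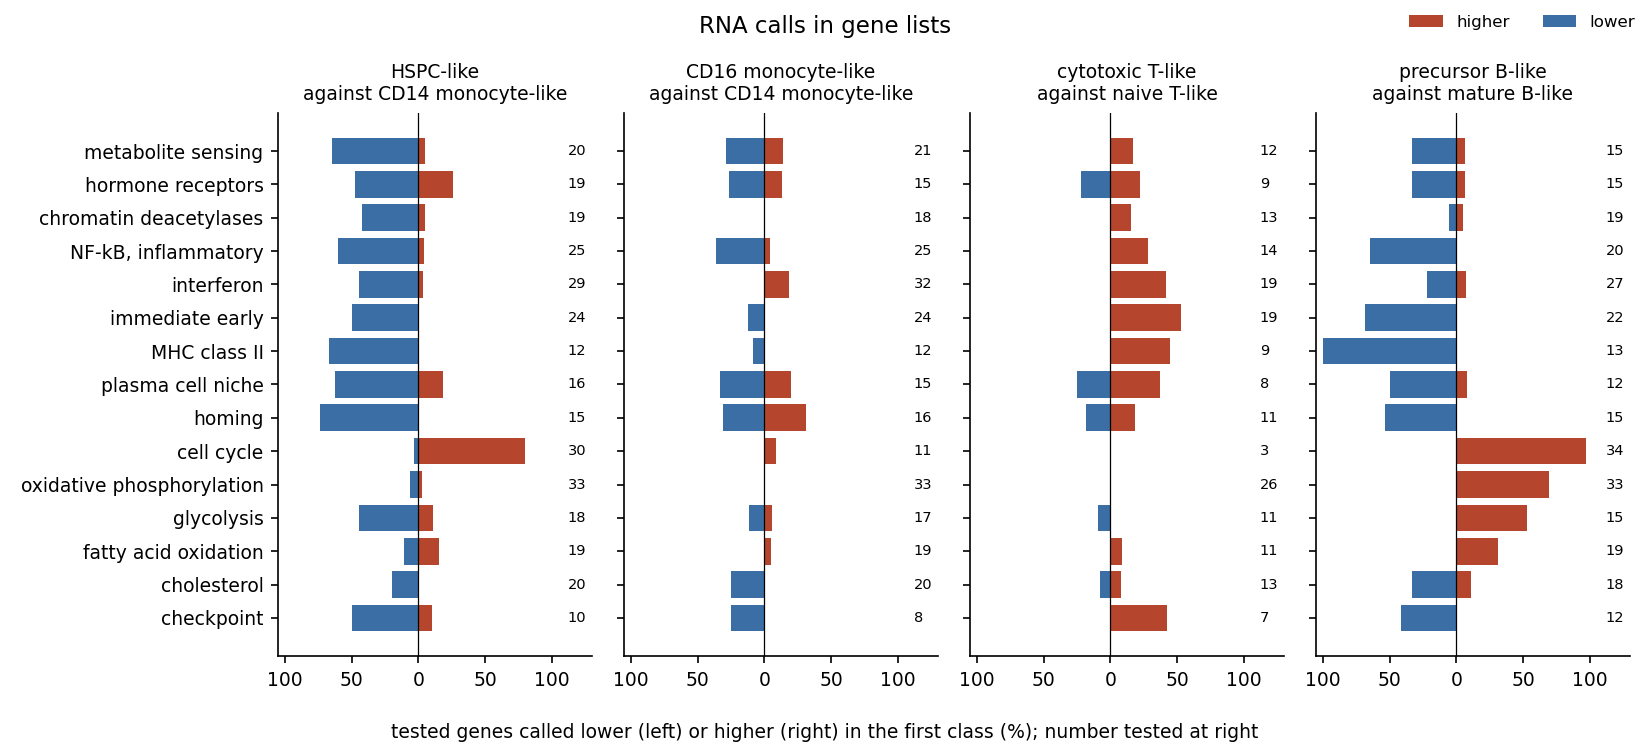
Share of each list's tested genes (%) called higher (red, to the right) or lower (blue, to the left) by RNA in the first class of each comparison, with the number of genes tested at the right of each bar. In precursor B-like cells 33 of 34 cell cycle genes are higher and 13 of 13 MHC class II genes are lower, while no list passes the set test with an estimated correlation.

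Accessibility was higher at 1607 and lower at 217 of 15473 genes in precursor B-like cells. The largest increases were at HMHB1 (log2 4.77, SE 0.490), NEURL1B (4.36, SE 0.375), TINCR (4.14, SE 0.660), FAM166C (3.87, SE 0.357), PALM2-AKAP2 (3.73, SE 0.398) and THBD (3.63, SE 0.518). The largest decreases besides CXCR5 were at SDCBP2 (-3.95, SE 0.818), IL1RN (-3.30, SE 0.774), ZPBP2 (-2.67, SE 0.626), ZBTB20-AS5 (-2.54, SE 0.480) and IL6 (-2.40, SE 0.394). Precursor markers opened, with IGLL1, a surrogate light chain gene, at 5.60 (SE 0.308) and VPREB1 at 3.81 (SE 0.410), each in 4 of 6 libraries. Of 10 precursor B markers 7 were called higher, as were 12 of 15 HSPC markers and 5 of 10 memory T markers, with 1 more of the latter lower. Of 12 mature B markers edgeR called 1 higher and 0 lower, with 0 lower past the fold limit at an unadjusted p under 0.05 and 0 called lower by DESeq2. Of 31 oxidative phosphorylation genes, a list with 23 RNA calls, edgeR called 0 in accessibility, with 0 past the fold limit at an unadjusted p under 0.05 and 0 called by DESeq2. Of 13 MHC class II genes 4 were lower. FFAR2, AHR, LEPR, ADIPOR1 and IL1B were at 0.19, -0.37, -0.69, 0.01 and 0.54, not called. TNF was at -0.94, under the fold limit, and was called without library 1 (-1.30), 6 (-1.12) or 8 (-1.01).

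By RNA, 9347 genes outside the clustering were tested in the B cell comparison, with 1778 higher and 1099 lower (n = 6). Of 15 lists 13 were called with a preset correlation and 0 with an estimated one. Of 11 HSPC markers 7 were higher in precursor B-like cells and 0 lower. The hemoglobin gene HBB, abundant in erythroid cells, was lower (log2 -1.15, SE 0.244), as was MALAT1 (-1.24, SE 0.156; 13686 against 31424 CPM). In the first project alone there were 706 accessibility and 1625 RNA calls; equal depths left 1782 RNA calls, and the stricter cell filter left 961 in accessibility.

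RNA and accessibility of the same genes moved together in all of the comparisons. Among genes with an RNA call, accessibility had the same sign for 78.5% in HSPC-like against CD14 monocyte-like cells, where the counts of signs alone would give 52.5%. The shares were 75.1% against 52.9% for the monocyte-like classes, 76.1% against 51.8% for the T cell classes and 63.6% against 48.6% for the B cell classes. Genes called in both numbered 651, 46, 41 and 307, and 623, 44, 41 and 290 of them had the same sign. Across all genes tested in both, Spearman's rho was 0.47, 0.26, 0.24 and 0.29; genes are not independent replicates.

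**Figure D3:**
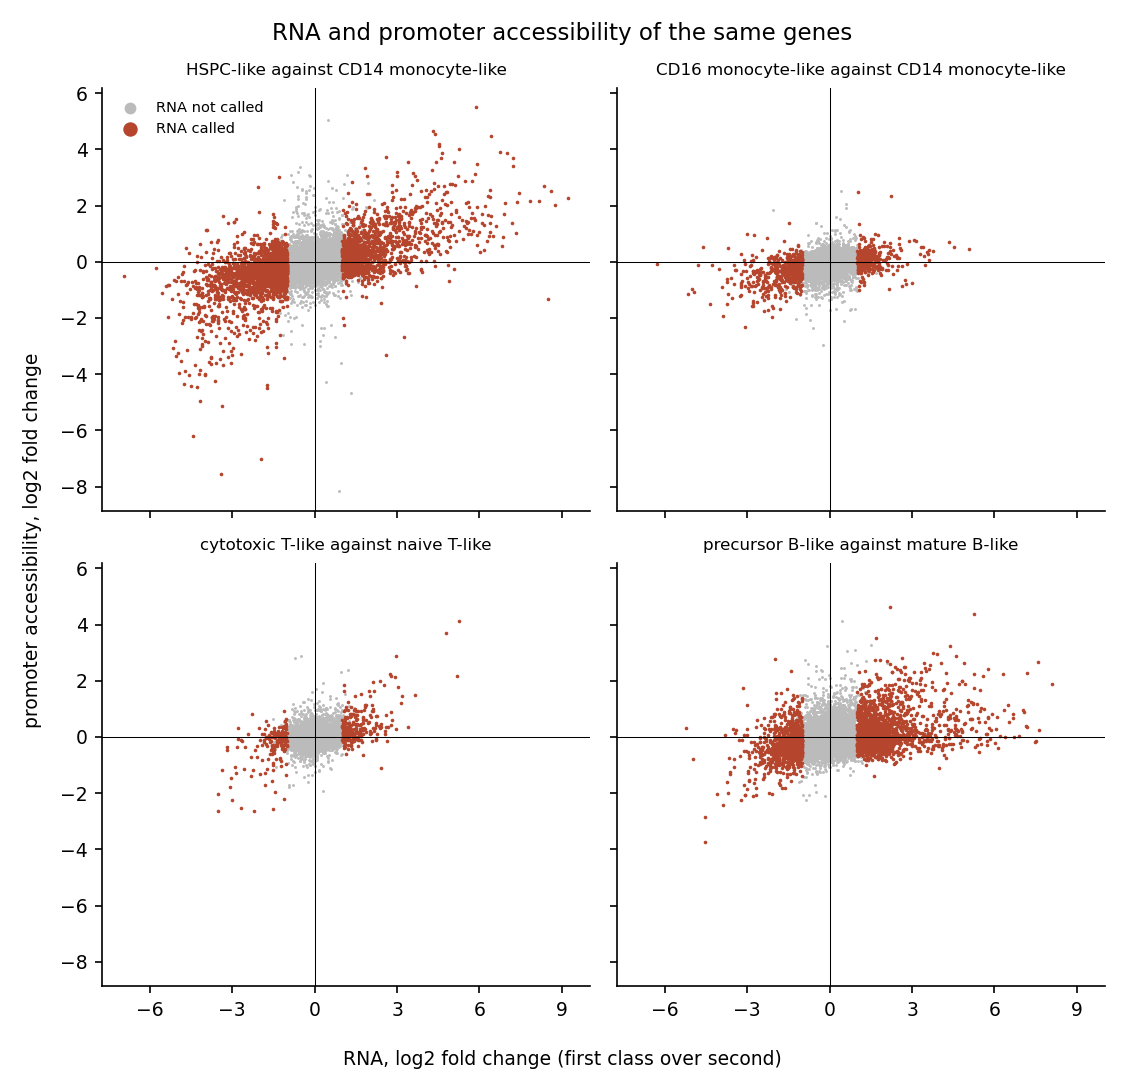
Log2 fold change of RNA (x axis) against log2 fold change of promoter accessibility (y axis) for each gene outside the clustering, first class over second, in 4 comparisons; red points are RNA calls and grey points are not called. Most red points lie in the lower left and upper right quadrants, with 78.5%, 75.1%, 76.1% and 63.6% of RNA calls of the same sign in accessibility.

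Metabolite and hormone sensing genes were read across 12 classes, since the study's title concerns diet, and the myeloid classes held most of the higher calls among metabolite sensors. cDC-like cells had 13 of 19 metabolite sensing genes higher than the mean of the other classes and 0 lower, CD14 monocyte-like cells 11 and 0, and CD16 monocyte-like cells 8 and 1. FFAR2 was higher in CD16 monocyte-like cells by log2 4.57 (SE 0.345, adjusted p = 5.01e-18; 34.7 ± 19.3 CPM, n = 5), in CD14 monocyte-like cells by 3.73 (SE 0.293) and in cDC-like cells by 2.46 (SE 0.461). Naive T-like cells held 0 FFAR2 UMIs, which allows up to 2.30 CPM. With predicted doublets kept, the cDC-like value was 0.76 and not called. GPBAR1, 268 bases from AAMP in the annotation, was highest in CD16 monocyte-like cells (4.67, SE 0.288). AHR was higher in CD14 monocyte-like (2.21, SE 0.166) and cDC-like cells (2.07, SE 0.188), and lower in plasma-like (-1.94, SE 0.274), erythroid-like (-1.77, SE 0.278) and precursor B-like cells (-1.24, SE 0.257).

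Single metabolite sensors were called in several classes. FFAR1, a receptor for long-chain fatty acids, was higher in mature B-like cells (log2 4.74, SE 0.326; 25.8 ± 7.98 CPM), and also in precursor B-like (2.64, SE 0.529, in 4 of 6 libraries) and cDC-like cells (2.45, SE 0.560, in 4 of 5). The annotation places it 541 bases from CD22, a mature B marker gene. CD36 was higher in pDC-like (4.01, SE 0.238), CD14 monocyte-like (3.54, SE 0.239), erythroid-like (3.38, SE 0.267), CD16 monocyte-like (1.35, SE 0.330) and cDC-like cells (1.23, SE 0.331). AHRR, the AHR repressor, was higher in cDC-like (3.78, SE 0.376) and CD14 monocyte-like cells (1.47, SE 0.331). TIPARP, an AHR target, was higher in NK-like (1.76, SE 0.175), cytotoxic T-like (1.21, SE 0.200) and cDC-like cells (1.19, SE 0.203). Of the 19 metabolite sensing genes tested 8 were lower in precursor B-like, 7 in erythroid-like, and 6 each in mature B-like and pDC-like cells. HSPC-like cells had 3 lower and naive T-like cells 4.

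Hormone receptors were spread over the classes. THRB was highest in HSPC-like cells (log2 4.85, SE 0.291). The estrogen receptor ESR1 was higher in plasma-like cells (4.22, SE 0.219; 331 ± 243 CPM, n = 6), as was INSR (2.23, SE 0.165). The annotation places ESR1 over a part of SYNE1. The growth factor receptor IGF1R was higher in naive T-like cells (2.47, SE 0.198). INSR was also higher in CD16 monocyte-like (1.45, SE 0.183) and precursor B-like cells (1.15, SE 0.191), and in cDC-like cells (1.01, SE 0.205), there under the fold limit without library 1, 3, 6 or 7 (0.84, 0.97, 0.96 and 0.77). It was lower in NK-like (-2.46, SE 0.294), cytotoxic T-like (-1.92, SE 0.329) and, in 5 of 6 libraries, naive T-like cells (-1.62, SE 0.308). LEPR, the leptin receptor gene, was lower in mature B-like cells (-1.43, SE 0.269) and higher in erythroid-like cells (2.10, SE 0.231), where LEPROT, which lies within it in the annotation, was also higher (1.68, SE 0.180). ADIPOR1, an adiponectin receptor gene, was called in CD14 monocyte-like cells at 1.00 (SE 0.159), which fell to 0.83 with DESeq2's size factors in edgeR and under the fold limit without library 3, 6 or 8 (0.92, 0.94 and 0.98).

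**Figure D4:**
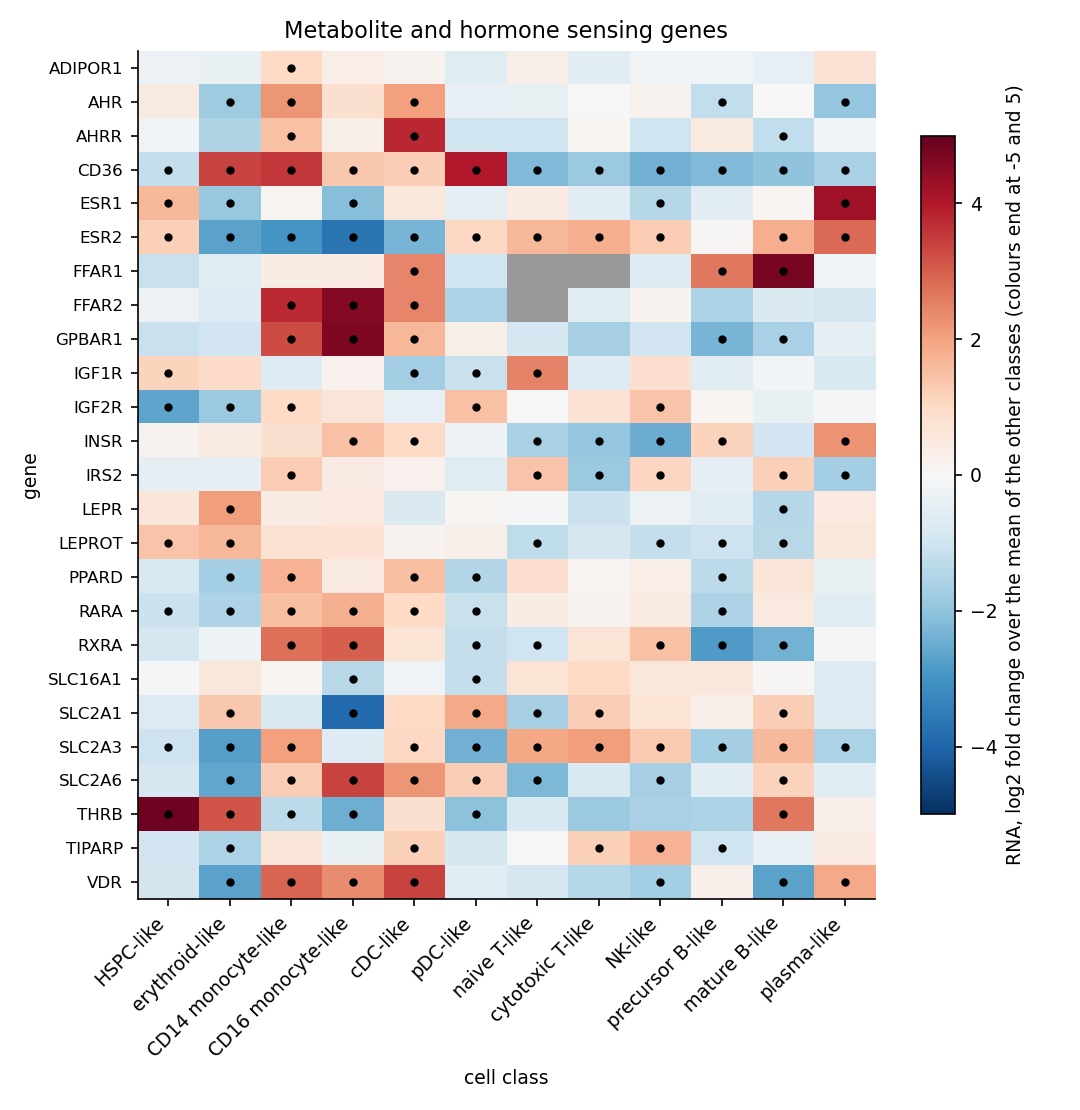
Log2 fold change of RNA in each cell class (columns) over the mean of the other classes for genes of the metabolite sensing and hormone receptor lists and for LEPR; colours end at -5 and 5, black dots mark calls, and grey marks a gene with 0 UMIs in the class. FFAR2 and GPBAR1 are higher in the monocyte-like classes, and ESR1 in plasma-like cells.

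Of 53 genes on the metabolite sensing and hormone receptor lists 36 had enough counts to be tested, and 34 were called in at least 1 class. Over 432 pairs of gene and class there were 95 higher and 79 lower calls. Adjusted over the list alone, the counts were the same in all classes except NK-like cells, where 10 rather than 9 genes on the hormone receptor list were called.

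Peak lists of the 12 libraries held 110083 ± 24159 peaks and covered 92841200 ± 20967300 bases, with a median peak length of 868 ± 7.57 bases. Of a list's peaks 93.8% ± 3.90 overlapped a peak of at least 1 other list by 1 base or more, and 37.3% ± 7.78 overlapped a peak in every other list. Lists of the third project held more peaks (140982 ± 3932, n = 4) than those of the first (94853 ± 11992, n = 3) and second (94503 ± 9462, n = 5). Merged over all lists there were 271739 regions, of which 84457 were in 1 list alone and 39234 in all 12. Lists shared 71.2% ± 5.28 of their peaks with a list of the same project and 65.1% ± 11.1 with a list of another project. The difference was 6.13 ± 13.6 percentage points (n = 12), from -11.1 to 25.4, and smaller than its spread. Such a share depends on the sizes of the lists compared, which differed between projects. The spread therefore does not show that the projects are alike.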

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

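The test of differences between sequencing projects and the tests of scaling with DESeq2's size factors were chosen after results were seen. A library was marked when its gap to the nearest other library was large for the range of its group. Chance marks about 1 in 20 groups, and here 22 of 247 groups, or 8.91%, were marked. Log2 values of single libraries use a prior count of 0.5, so the largest of them, from few or 0 counts, depend on it.

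In class shares, 1 library stood apart with 13.7% HSPC-like cells (0.282% to 3.57% in the others) and 1 with 14.8% pDC-like cells (1.24% to 4.95%). A library with 4.32% cytotoxic T-like cells stood above the others at 2.29% to 2.78%.

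Between HSPC-like and CD14 monocyte-like cells, accessibility decreased less in 1 library each at C2orf91 (log2 -2.62, others -7.22 to -6.02), MNDA (-2.41, others -7.64 to -6.91) and HAL (-2.51, others -7.58 to -7.03). TNF accessibility was at -7.87 in 1 library and -3.75 to -2.26 in the others. By RNA, TNFAIP2 was at -10.09 (others -5.12 to -3.23), UQCRC1 at -7.81 (others -1.95 to -0.19) and TYMS at 1.504 (others 4.42 to 5.32) in 1 library each.

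Between the monocyte-like classes, accessibility of MYBPHL was at 2.31 in 1 library (others 0.82 to 1.22) and that of HCAR2 at -7.78 (others -0.75 to -0.36). By RNA, CX3CR1 was at 3.81 (others 1.40 to 1.82), PFKP at -7.17 (others -2.57 to -1.001) and CENPE at 7.43 (others 0.01 to 2.04). FFAR2 was at -0.94 in the library where it was lower in CD16 monocyte-like cells, and at 0.66 to 0.94 in the others.

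In the lymphoid comparisons, SC5D was at -0.90 in 1 library for the T cell classes (others -2.89 to -2.21). For the B cell classes, FAM166C accessibility was at 1.58 (others 3.75 to 4.55) and FFAR2 accessibility at -5.35 (others -0.58 to 2.11). Across classes, SLC2A1 in CD16 monocyte-like cells was at -0.99 in 1 library (others -3.85 to -3.03), FFAR2 there at 2.50 (others 4.32 to 4.95), and IRS2 in plasma-like cells at -7.26 (others -2.46 to -0.79).

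The class difference in RNA also differed between the sequencing projects for 13 genes in HSPC-like against CD14 monocyte-like cells, 4 in the T cell classes and 3 in the B cell classes, by an interaction term in edgeR. For the monocyte-like classes edgeR gave 0 genes, with 456 at an unadjusted p under 0.05. In accessibility it gave 0 in each of the 4 comparisons, with 808, 537, 598 and 626 at an unadjusted p under 0.05. No other tool was run for this term. In the B cell classes the genes were JUN (-2.77), TYMS (3.77) and UBE2C (4.11), as log2 in the second project minus the first.

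The T cell genes were the immediate early genes FOS (2.25), JUN (1.66) and DUSP2, and RGCC (2.20), with cytotoxic minus naive means in the first and second project of 0.01 and 2.16, -0.29 and 1.41, 1.07 and 2.88, and -1.005 and 1.23. DUSP2 differed by 1.89 (SE 0.393, adjusted p = 0.045). Handling of whole libraries may raise immediate early RNA in all cells, which would put the second project above the first in naive T-like cells and in most classes. The median difference of the list in naive T-like cells was -0.876, and 5 of 12 classes were above 0, so no rise in most classes was seen. The naive T-like value is itself part of the difference that flagged these genes. A rise equal in all classes would also cancel in that difference. The test therefore cannot decide whether handling played a part. Project and participants cannot be told apart here, since no participant had cells in both, and no biological explanation was tested.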

How the results depend on the processing

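Alternatives chosen after the data were seen were whole genes with 1 kb flanks, fragments instead of cut sites, scaling over all libraries and equal depths. A count was taken as changed when it moved by more than 1.5 times, and a share when it moved by more than 1 SD of the libraries. A sign was taken as reversed only for a called value or one more than 1 SE from 0.

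With no library block, accessibility calls fell to 1694 for HSPC-like against CD14 monocyte-like cells, 100 for the monocyte-like classes and 188 for the T cell classes, and RNA calls to 431 and 281 for the last 2 of these. The first sequencing project alone gave 1439, 26, 0 and 706 accessibility calls in the order HSPC, CD16 monocyte, T and B cell comparison, from fewer libraries; the 0 is by edgeR, with 314 at an unadjusted p under 0.05, and DESeq2 was not run on it. It gave 2485, 137 and 1625 RNA calls in the HSPC, T and B cell comparisons. The strict cell filter gave 5 accessibility calls for the monocyte-like classes in 2 libraries, 46 for the T cell and 961 for the B cell classes, and 242 RNA calls for the T cell classes. Equal depths left 2347 and 1782 RNA calls in the HSPC and B cell comparisons, where fewer genes were tested, 5967 and 5460. Whole genes gave 538 accessibility calls for the T cell classes, and the cause was not tested.

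DESeq2's test gave 2606, 361, 394 and 2029 accessibility calls and 3861, 934, 408 and 2801 RNA calls. With libraries left out in turn, accessibility calls ranged from 2003 to 2909, 221 to 401, 179 to 367 and 1444 to 1937, with 221 without library 7 for the monocyte-like classes and 218 and 179 without libraries 6 and 8 for the T cell classes. RNA calls ranged from 3108 to 3969, 808 to 1165, 380 to 628 and 2396 to 3346, and receptor calls from 152 to 178. Receptor calls stayed within 1.5 times of 174 under each alternative run. For receptor genes across classes, the strict cell filter, DESeq2's test, no library block, equal depths and scaling over all libraries were not run. The strict filter lowered the shares of cDC-like and CD14 monocyte-like cells, as given below. Whether receptor calls of these classes hold under it was not tested.

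Of the class shares, the strict filter moved CD14 monocyte-like cells to 5.74%, cDC-like and myeloid progenitor-like cells to 0%, naive T-like cells to 6.70%, pDC-like cells to 12.03% and plasma-like cells to 12.01%. Myeloid progenitor-like cells were 0.778% at resolution 0.5 and 0.739% at resolution 2, and naive T-like cells 6.23% at resolution 2. Leaving libraries out gave ranges of 19.1% to 26.1% for CD14 monocyte-like, 3.25% to 6.74% for CD16 monocyte-like, 1.45% to 4.13% for HSPC-like, 6.36% to 7.44% for NK-like, 1.75% to 2.66% for cDC-like and 2.60% to 3.00% for cytotoxic T-like cells. They were 0.959% to 1.47% for erythroid-like, 25.2% to 33.5% for mature B-like, 0.250% to 0.363% for myeloid progenitor-like, 2.58% to 3.38% for naive T-like, 2.70% to 5.41% for pDC-like, 3.17% to 6.43% for plasma-like, 2.17% to 3.57% for precursor B-like and 7.76% to 10.5% for unnamed cells. Peaks shared with any other list ranged from 93.4% to 94.7% and with all others from 36.3% to 38.2%.

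Of 222 called gene results counted here, 3448 of 3679 values under alternatives kept sign and call, 227 kept the sign only and 4 reversed. Whole genes reversed accessibility of PALM2-AKAP2 (-0.27) and SRI (0.29) in HSPC-like cells and of INSR (-0.18) in precursor B-like cells. HLA-DQB1 RNA in cytotoxic T-like cells was at -0.92 with doublets kept. Of 77 results not called, 1467 of 1496 values kept sign and call, 19 were called and 10 reversed. In accessibility, the first project alone put ERG in HSPC-like cells at -0.0397, LEPR and FCN1 in CD16 monocyte-like cells at -0.11 and 0.0828, and ADIPOR1 in cytotoxic T-like cells at 0.0524. Windows of 5 kb put FFAR2 in CD16 monocyte-like cells at 0.0580, whole genes put INSR in cytotoxic T-like cells at 0.0402 and FCRL1 in precursor B-like cells at 0.16, and the strict filter put RALGPS2 in precursor B-like cells at 0.0399. By RNA, AHR in cytotoxic T-like cells was at -0.15 with doublets kept and -0.00953 under the strict filter. The causes were not tested.

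The strict filter for HSPC-like against CD14 monocyte-like cells and start intervals of at most 5 kb were not run. For receptor genes across classes, the strict filter and the other alternatives named above as missing were not run either. The T cell comparison had the fewest RNA genes tested, 4670.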

Other observations

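The tests of scaling between classes with DESeq2's size factors, and the use of splits that part every library alone, were chosen after the result was seen. Since the classes are paired in each library, a real split was compared with all splits that part every library. With 6 libraries there are 32, and 1 of 32, the real one, reached the count in each case. For the T cell classes the real and highest other counts were 349 and 145 in accessibility and 523 and 74 by RNA, and for the B cell classes 1824 and 385, and 2877 and 367. With 5 libraries there are 16, too few for a share under 0.05. The counts there were 2646 and 0 in accessibility and 4000 and 0 by RNA for HSPC-like against CD14 monocyte-like cells, and 359 and 13, and 1016 and 6, for the monocyte-like classes. Among 80 splits drawn over all samples, those that leave some libraries unparted reached up to 2146, 273, 275 and 1364 calls in accessibility and 2219, 980, 451 and 2119 by RNA, in the order HSPC, CD16 monocyte, T and B cell comparison. For receptor genes 1 of 22 relabellings, the real one, gave 174 calls, and the highest other gave 10. The classes were clustered from RNA of the same cells, which favours the real split in advance, so these counts do not show that chance can be excluded for the class differences.

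Accessibility calls were one-sided in 2 comparisons, with 93.0% lower in CD16 monocyte-like cells and 88.1% higher in precursor B-like cells. Unequal depth of the classes could produce this, but with equal depths the shares were 91.8% and 89.2%. The scaling between classes could too. With DESeq2's size factors the shares were 93.1% and 91.0%, but these factors, like TMM, take most genes as unchanged, so they cannot settle it. A loss or gain of accessible chromatin over the whole genome, which any scaling removes, stays open, and no biological explanation was tested.

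Oxidative phosphorylation RNA was higher in precursor B-like cells in a way that a larger cytoplasmic RNA share might give. Then ribosomal protein genes would rise as much, but the oxidative phosphorylation median exceeded theirs in 6 of 6 libraries, at 1.31 against 0.55 over all, which argues against it as the only source. The nuclear RNA MALAT1 fell (log2 -1.24, SE 0.156, in 6 of 6 libraries), as it also would, so a part of the rise from this source stays open. Unequal depth is argued against too, since 91.3% of the calls, 21 of 23, were kept at equal depths. Precursor B-like clusters of 236 and 55 cells had MKI67 and TOP2A among their top genes, while those of 219 and 170 cells did not. Median UMIs per cell were 4376 and 8517 in the former, and 922 and 1441.5 in the latter. The cycling cells as a source of the rise stay open as well, and no biological explanation was tested.

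A hypothesis that genes with an RNA call move the same way in accessibility was tested with the accessibility differences of each library. RNA calls and their signs came from the fit over all libraries, so the libraries are not separate tests. The share of the same sign exceeded that given by counts of signs by at least 19.4, 10.9, 9.17 and 9.04 percentage points in the HSPC, CD16 monocyte, T and B cell comparisons, which is consistent with it.

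Genes of the plasma cell niche list were also read in each class against the mean of the others, as values outside the comparisons. Plasma-like cells had higher RNA of the receptor gene TNFRSF13B (log2 7.03, SE 0.305), the growth factor gene IGF1 (6.68, SE 0.283) and HGF (4.18, SE 0.276, in 5 of 6 libraries). TNFRSF13B was also higher in mature B-like cells (4.53, SE 0.329), and HGF in CD16 monocyte-like (3.30, SE 0.318) and CD14 monocyte-like cells (2.02, SE 0.286). The survival factor gene TNFSF13B was higher in cDC-like (2.44, SE 0.181), CD14 monocyte-like (2.16, SE 0.155), CD16 monocyte-like (2.14, SE 0.184) and pDC-like cells (1.47, SE 0.182). TNFSF13 was higher in CD14 monocyte-like (2.60, SE 0.224), CD16 monocyte-like (2.41, SE 0.279), cDC-like (1.90, SE 0.314) and, in 5 of 6 libraries, pDC-like cells (1.08, SE 0.317). IL6R was highest in CD14 monocyte-like cells (3.03, SE 0.200), and VEGFA in cDC-like cells (3.57, SE 0.270).

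All 33 cell cycle genes tested were higher in erythroid-like and in precursor B-like cells than in the mean of the other classes. All 13 MHC class II genes were higher in cDC-like and mature B-like cells and lower in NK-like and erythroid-like cells. Interferon response genes were most often higher in CD16 monocyte-like cells (18 of 31) and cytotoxic T-like cells (12 of 31, with 1 lower), and immediate early genes in NK-like cells (12 of 23, with 1 lower).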
